A study of Mus musculus with 24 samples.

How the data were processed

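RNA was sequenced from 24 libraries of female mice aged 12 weeks, wildtype (WT) or knockout (KO) for Prxl2a. Inguinal adipose tissue (IAT), dorsal brown adipose tissue (BAT), brain and liver gave 6 libraries each, with 3 WT and 3 KO libraries per tissue. Per the labels' protocols, mice were perfused with PBS before the tissues were taken and frozen. The design text states 3 mice per group, so the tissues may come from the same mice.

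The authors deposited 1 table of 19015 genes, of which 2 kinds of value per library were used here. The expected counts are estimated reads per gene, not normalised, per the file headers. The TPM values were made by the authors within each library, per the file headers. Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and genome build GRCm38.p6 are named in the submitters' processing notes. The annotation and any filters are not given in the sources used here. Gene identifiers matched the reference annotation for 18958 genes, which is 99.7% of the table, and 57 did not match. A further 48 per-sample columns of the table were not used.

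Expected counts were rounded to whole numbers. Each tissue was tested on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter and the quasi-likelihood F-test for KO against WT. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Standard errors on the log2 scale were taken from the F statistic. CPM values were normalised within each tissue by TMM, except where the 12 WT libraries were compared across tissues. Differences between tissues were tested in 1 fit of the 24 libraries with an F-test on 3 degrees of freedom. Sharing of changed genes between tissues was tested with a two-sided Fisher's exact test over the genes tested in both.

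Before the data were examined, 39 gene lists were fixed for the pathways and cell types these tissues could hold, along with the tests and the rule for named genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

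Named genes were Prxl2a in every tissue, up to 8 rises and 8 falls per tissue among called genes with a plain symbol, a mean of at least 5 CPM and no overlap between the groups, and up to 4 called members of each list. Where a list had no called member, up to 2 with the smallest unadjusted p could be given as values. Where fewer than 10 genes were called in a tissue, up to 6 further genes could be given as not passing. Up to 10 genes changed alike in several tissues, up to 8 genes whose change differed between tissues, and a few marker genes per tissue completed the set. The result of 1 gene that this rule names is not reported here.

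Alternatives were RLE normalization, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, all 24 libraries in 1 fit, the replicate number as a block, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, an absolute log2 fold change of at least 1, and leaving out each library. After seeing the data, a robust dispersion prior, marker levels as covariates and the joint removal of IAT libraries rich in lymphocyte or muscle transcripts were added.

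Library totals were 16147508 to 17323714 counts in IAT, 12327459 to 12948149 counts in BAT, 15788266 to 17293215 counts in brain and 17034043 to 18257788 counts in liver. Pearson correlations of log2 CPM between replicates were 0.938 to 0.993 across genes, and no pair of libraries matched within sampling noise. The tests were tested on simulated data drawn from the real means, with 200 genes changed. Of 66 genes changed 4-fold, 56 were recovered in IAT, 64 in BAT, 62 in brain and 64 in liver. Of 67 genes changed 2-fold, 6 were recovered in IAT, 53 in BAT, 49 in brain and 59 in liver. The simulated genes varied independently, with a dispersion set by their mean and without transcripts of other cell types in single libraries. These counts can therefore overstate recovery in real libraries, above all in IAT, where Prxl2a itself did not pass (edgeR adjusted p = 0.0912).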

Results

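Transcripts of 4 tissues were compared between WT mice and mice lacking Prxl2a, which encodes a peroxiredoxin-like protein. Each of the 8 groups held 3 libraries, and library totals ran from 12327459 counts in BAT to 18257788 counts in liver.

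Prxl2a (gene 70564, GRCm38.p6 chromosome 14, 40993735 to 41013833) was first compared in every library, as a check of the genotype labels. In BAT it averaged 492 CPM in WT (SD 17.9, n = 3) and 22.4 CPM in KO (SD 3.40, n = 3), and it fell by 4.45 on the log2 scale (SE 0.13, edgeR adjusted p = 1.09e-05). In brain it averaged 104 CPM in WT (SD 17.8) and 5.74 CPM in KO (SD 0.53), and it fell by 4.17 (SE 0.16, edgeR adjusted p = 0.000131). In liver it averaged 78.5 CPM in WT (SD 9.46) and 1.55 CPM in KO (SD 0.59), and it fell by 5.65 (SE 0.21, edgeR adjusted p = 1.08e-05). In IAT the means were 390 CPM in WT (SD 101) and 16.3 CPM in KO (SD 7.03), with a log2 fold change of -4.58 (SE 0.41) that did not pass in edgeR (adjusted p = 0.0912). The IAT value passed with DESeq2 (adjusted p = 2.17e-27), with limma-voom (adjusted p = 0.0470), with all 24 libraries in 1 edgeR fit (adjusted p = 9.87e-09), without WT replicate 1 (adjusted p = 0.0271) and without KO replicate 2 (adjusted p = 0.00213). Every KO library lay below every WT library in each tissue. The KO libraries kept 4.19% of the WT mean in IAT, 4.56% in BAT, 5.54% in brain and 1.98% in liver. The change was not called different between tissues (edgeR interaction adjusted p = 0.153).

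**Figure D1:**
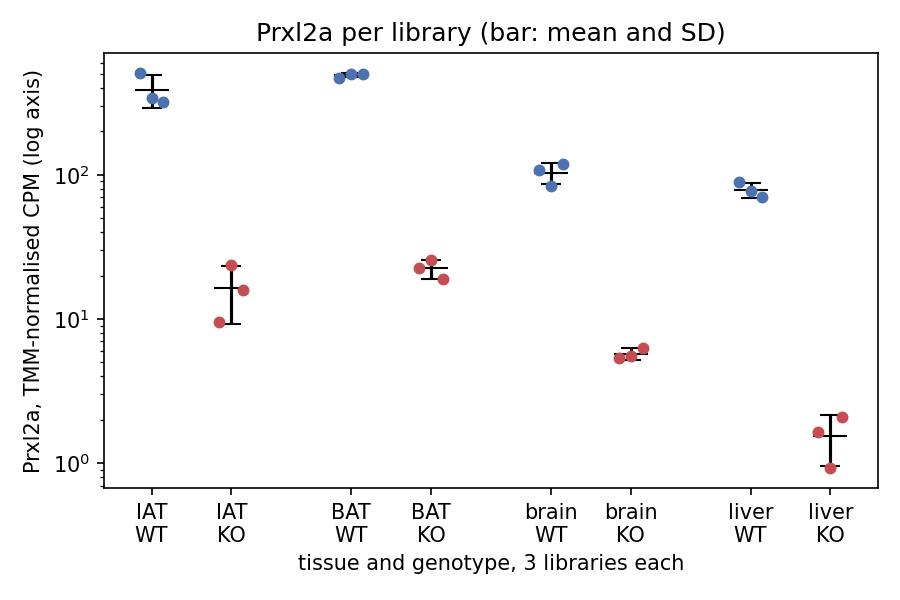
Prxl2a in each library as TMM-normalised CPM on a log axis, by tissue and genotype. Points are libraries, and the black marks are the mean and SD of 3 libraries. KO means were 16.3 CPM in IAT, 22.4 in BAT, 5.74 in brain and 1.55 in liver.

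Among the 12 WT libraries, normalised together, Prxl2a was highest in BAT, at 488 CPM (SD 15.3, n = 3), followed by IAT at 304 CPM (SD 77.5), liver at 135 CPM (SD 16.1) and brain at 77.3 CPM (SD 13.2). The tissues differed in edgeR (adjusted p = 1.96e-07), and BAT lay 2.66 above brain on the log2 scale. Normalised within each tissue, the WT means were 104 CPM in brain and 78.5 CPM in liver, so the order of these 2 tissues depends on the normalization.

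In IAT, the comparison of KO with WT was marked by transcripts of other cell types in some libraries. The lymphocyte list averaged 7.19 log2 CPM in KO replicate 1 and 6.20 in KO replicate 3, against -0.78 in KO replicate 2 and -0.54 to 0.47 in the WT libraries. Fcer2a, a B cell IgE receptor, stood at 137 CPM in KO replicate 1 and 71.2 CPM in KO replicate 3, and at 0.82 CPM in KO replicate 2. The skeletal muscle list averaged 5.60 in WT replicate 1 and 7.32 in WT replicate 2, against 0.09 in WT replicate 3 and 0.29 to 1.14 in the KO libraries. Tnnt3, a troponin of fast muscle, stood at 143 CPM and 538 CPM in those WT libraries and at 0.96 CPM in WT replicate 3.

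**Figure D2:**
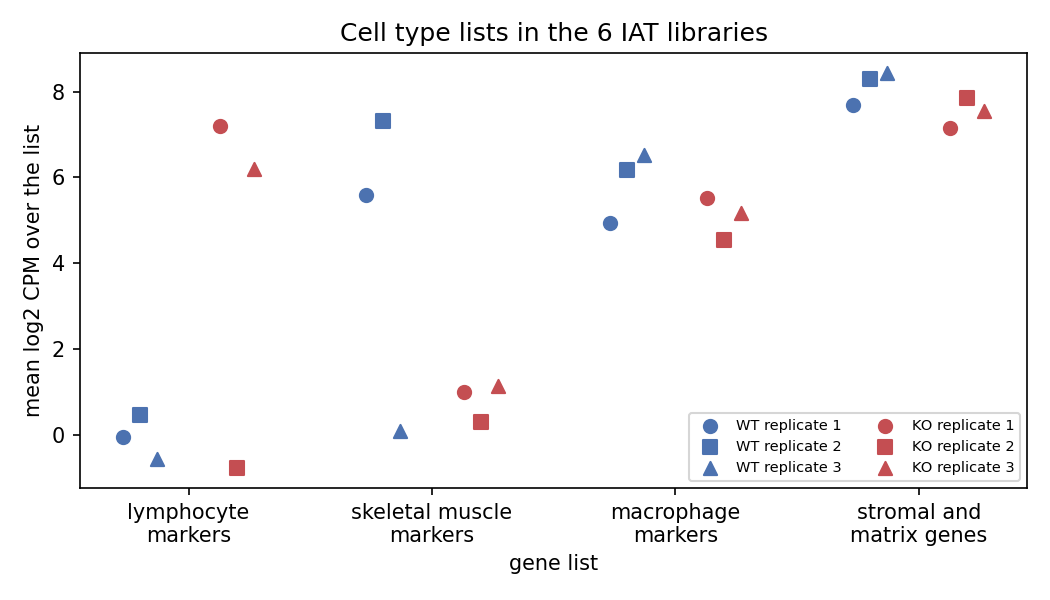
Mean log2 CPM of 4 gene lists in each of the 6 IAT libraries, with colour for genotype and shape for replicate number. Lymphocyte markers were at 7.19 and 6.20 in KO replicates 1 and 3 and at -0.78 in KO replicate 2.

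Among the IAT lists, 2 were higher and 9 lower in KO by camera, of 23 tested. Without KO replicates 1 and 3, an alternative chosen after seeing the data that assumes the lone KO library varies like the others, 8 were higher and 4 lower. In that lone KO library the lymphocyte list averaged -0.78 log2 CPM, against -0.54 to 0.47 in the WT libraries. The cell cycle list stood there at 2.29, against 1.74 to 2.73 in the WT libraries. Without WT replicates 1 and 2, chosen likewise, 2 lists were higher and 7 lower, and the muscle list was not called (adjusted p = 0.0620, alternatives 4.03e-29 to 0.834). As differences of group means in log2 CPM, the lymphocyte list went from 4.24 to 2.75 without KO replicate 1 and to 6.73 without KO replicate 2, the cell cycle list from 1.21 to 0.80 without KO replicate 1, and the muscle list from -3.52 to -2.03 without WT replicate 2 and to -5.64 without WT replicate 3. No list was called with an estimated correlation, and the smallest p there was that of the immediate early genes (adjusted p = 0.153 with an estimated correlation). The immediate early list had a median log2 fold change of -0.46, with 15 of 21 members lower, 8 down adjusted over the list alone and 0 over all genes. Egr1 had -1.80 (SE 0.22, n = 3 per group) and Atf3 -1.74 (SE 0.14), both transcription factors induced by stimulation, and neither passed over all genes. This list was also called by fry (adjusted p = 0.0263). All other called lists had adjusted p = 0.834 with an estimated correlation. The lymphocyte list had a median of 5.84 with 22 of 22 members higher, 22 adjusted over the list alone and 0 over all genes, and the cell cycle list a median of 1.47 with 26 of 26 higher and 0 by either adjustment. Ccna2, a cyclin, had 1.47 (SE 0.47) and Nusap1 1.36 (SE 0.43), and the cell cycle list stood at 4.16 and 3.55 log2 CPM in KO replicates 1 and 3 and at 2.29 in KO replicate 2. The muscle list had a median of -5.49 with 12 of 17 down adjusted over the list alone, and 0 over all genes.

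Lists of metabolic genes and of other cells were also lower in KO IAT by camera, and none of them was called with an estimated correlation. All 74 tested oxidative phosphorylation subunits had lower values (median -0.25), among them Ndufa11 at -0.43 (SE 0.20), with 0 passing adjusted over the list alone. This list stood at 6.69 and 6.95 log2 CPM in KO replicates 1 and 3 and at 7.41 in KO replicate 2, above WT replicates 2 and 3 at 7.22 and 7.17. Its difference of group means went from -0.28 to -0.18 without WT replicate 1, to -0.12 without KO replicate 1 and to -0.48 without KO replicate 2. Without KO replicates 1 and 3 it was higher in KO (camera adjusted p = 0.00128), and without WT replicates 1 and 2 it was not called (adjusted p = 0.0690, alternatives 1.17e-12 to 0.834). The lipogenesis list had a median of -0.67, with Me1, which makes cytosolic NADPH, at -1.85 (SE 0.52) and Acss2 at -1.60 (SE 0.47), and 0 passing by either adjustment. It stood at 10.65 in WT replicate 1 and at 9.10 to 9.72 in the other libraries, and its difference of group means went from -0.66 to -0.33 without WT replicate 1. The thermogenic list had a median of -0.56, with the adrenergic receptor Adrb3 at -1.06 (SE 0.31), and the NRF2 target list a median of -0.34, with Tkt at -1.28 (SE 0.41). The thermogenic list was highest in WT replicate 1, at 4.15 against 2.76 to 3.45, and was not called without that library (camera adjusted p = 0.653) or without KO replicate 1 (adjusted p = 0.176, alternatives 7.14e-05 to 0.834). Its difference of -0.45 became -0.14 and -0.28 without these, and -0.71 without WT replicate 3. The NRF2 list stood at 6.77 and 7.10 in KO replicates 1 and 3 and at 7.48 in KO replicate 2, and was not called without KO replicate 1 (camera adjusted p = 0.176, alternatives 6.03e-05 to 0.834). Its difference of -0.34 became -0.16 without KO replicate 1 and -0.52 without KO replicate 2. The macrophage list had a median of -1.29, with 7 members down adjusted over the list alone, Adgre1 at -1.62 (SE 0.36) and Cd163 at -1.41 (SE 0.32). It stood at 4.93 in WT replicate 1, below KO replicates 1 and 3 at 5.52 and 5.16, and its difference of group means went from -0.80 to -1.27 without WT replicate 1 and to -0.47 without WT replicate 3. The stromal and matrix list had a median of -0.70, with 3 down adjusted over the list alone, Pi16 at -1.52 (SE 0.26) and Fn1 at -1.34 (SE 0.30). The mammary epithelium list had a median of -0.46, with Krt19 at -1.11 (SE 0.27), and was not called without WT replicate 1 (camera adjusted p = 0.354) or KO replicate 1 (adjusted p = 0.0844, alternatives 2.61e-05 to 0.834). Its difference of -0.37 became -0.23 without WT replicate 1 and -0.59 without WT replicate 3. Without KO replicates 1 and 3 together, the lipogenesis, thermogenic, NRF2, stromal and mammary lists were not called (camera adjusted p = 0.328, 0.831, 0.249, 0.492 and 0.499), where the alternatives ran from 7.72e-08 to 0.834 for lipogenesis and from 2.56e-09 to 0.834 for the stromal list. Without WT replicates 1 and 2 together, the thermogenic and mammary lists were not called (camera adjusted p = 0.579 and 0.693). Of these lists, 0 members passed over all genes. The adipocyte genes Adipoq at -0.02 (SE 0.43), Pparg at 0.03 (SE 0.46), Lep at 0.66 (SE 0.51) and Fasn at -1.21 (SE 0.60) did not pass, and Ucp1 was at 0.38 CPM in WT.

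Of 14097 genes tested in IAT, edgeR called 0, with 2226 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0855. DESeq2 called 987, limma-voom 7 and the fit of all 24 libraries 2573, while edgeR called 192 without WT replicate 1 and 1760 without KO replicate 2. KO and WT libraries did not overlap for 18.5% of genes, and for 25.6% in BAT, 12.5% in brain and 21.6% in liver. The mean over random groupings is 10%. Genes vary together, so a single grouping can lie far from that mean, and the shares of other groupings were not computed. Splits of the 6 libraries that mix the genotypes called up to 15 lists by camera.

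In BAT, 49 genes rose and 19 fell, of 12588 tested. The largest rises by the naming rule included E2f2, a transcription factor of the cell cycle, at 2.66 (SE 0.23, edgeR adjusted p = 0.00950, n = 3 per group), Dusp14 at 2.23 (SE 0.26), Ripor2 at 2.04 (SE 0.20), Kit, the receptor for stem cell factor, at 1.71 (SE 0.19), Rab4a at 1.62 (SE 0.19), Dixdc1 at 1.54 (SE 0.23) and Slc19a1, the reduced folate carrier, at 1.24 (SE 0.14). The largest falls after Prxl2a included Apcdd1 at -2.01 (SE 0.32), Gdf5, a BMP family ligand, at -1.67 (SE 0.21), Hcar2, the niacin receptor, at -1.47 (SE 0.20), Exd1 at -1.22 (SE 0.16) and Adcy9, an adenylyl cyclase, at -1.04 (SE 0.14). Of the fixed lists, Hspa8, a constitutive heat shock chaperone, rose by 1.09 (SE 0.15, edgeR adjusted p = 0.0329), and Atf5, a factor of the integrated stress response, fell by 0.72 (SE 0.11, edgeR adjusted p = 0.0483).

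By camera, 3 BAT lists were higher and 2 lower, of 22 tested, and none was called with an estimated correlation (adjusted p = 0.812 with an estimated correlation for each of them). Oxidative phosphorylation subunits were higher in 72 of 74 (median 0.17), with Ndufv3 at 0.31 (SE 0.08) and 0 passing by either adjustment. The chaperone and heat shock list had 19 of 26 higher (median 0.27), with 1 up by either adjustment. It stood at 7.06 log2 CPM in KO replicate 3 and at 6.29 to 6.51 in the other libraries, and was not called without KO replicate 3 (camera adjusted p = 0.0704) or WT replicate 2 (adjusted p = 0.0811, alternatives 0.00486 to 0.812). Its difference of group means went from 0.32 to 0.12 without KO replicate 3. The cholesterol synthesis list had 14 of 21 higher (median 0.22), with 5 up adjusted over the list alone and 0 over all genes, including Cyp51 at 0.64 (SE 0.11) and Hsd17b7 at 0.75 (SE 0.15). This list was not called without WT replicate 2 (camera adjusted p = 0.201), WT replicate 3 (0.102), KO replicate 1 (0.0752) or KO replicate 2 (0.146, alternatives 0.000708 to 0.812). Its difference of 0.20 became 0.30 without WT replicate 1, 0.11 without WT replicate 2 and 0.12 without KO replicate 2. The stromal and matrix list had 25 of 29 lower (median -0.52), with 12 down and 1 up adjusted over the list alone and 0 over all genes, including the collagens Col3a1 at -1.06 (SE 0.18) and Col6a3 at -0.56 (SE 0.10). The macrophage list had 21 of 21 lower (median -0.54), with Cd14 at -0.49 (SE 0.15) and 0 passing by either adjustment. It stood at 3.67 log2 CPM in WT replicate 1 and at 2.38 to 2.75 in the other libraries, and was not called without that library (camera adjusted p = 0.0995, alternatives 7.19e-06 to 0.812). Its difference of -0.50 became -0.18 without WT replicate 1. The stromal list was likewise highest in WT replicate 1, at 6.27, and its difference of -0.40 became -0.25 without that library. Muscle markers were at 6.44 in that library and at -0.58 to 2.70 in the others.

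Ucp1, which uncouples brown fat mitochondria, had a log2 fold change of 0.32 (SE 0.22) and Ucp3 0.74 (SE 0.15), and neither passed. Adipoq at 0.05 (SE 0.08), Pparg at 0.28 (SE 0.09), Lep at 0.16 (SE 0.40) and Fasn at -0.23 (SE 0.29) did not pass either. The edgeR count of 68 became 37 without WT replicate 1, 5 without WT replicate 2, 2 without WT replicate 3, 3 without KO replicate 2 and 42 without KO replicate 3, and DESeq2 called 467. The count of lists became 8 without WT replicate 1, and splits that mix the genotypes called up to 11 lists.

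**Figure D3:**
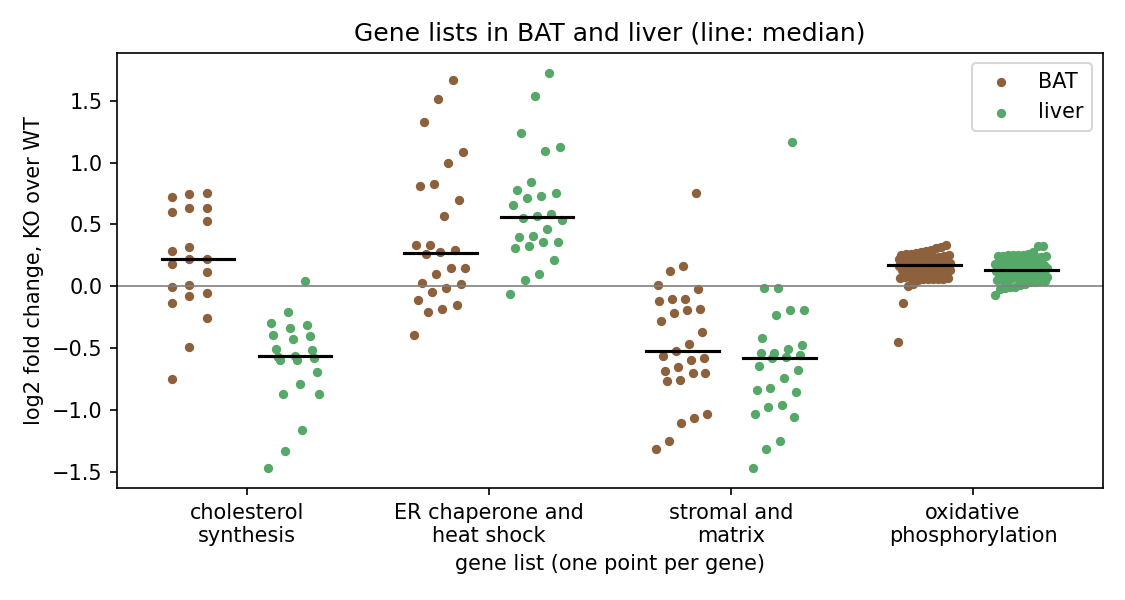
Log2 fold change of each tested member of 4 gene lists in BAT and liver, with 1 point per gene and a line at the median. Cholesterol synthesis genes had a median of 0.22 in BAT and -0.57 in liver.

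In brain, 2 genes rose and 5 fell, of 14385 tested. Wdfy1, a phosphoinositide-binding adaptor, rose by 1.17 (SE 0.12, edgeR adjusted p = 0.0314, n = 3 per group), and Nnt, the mitochondrial transhydrogenase that makes NADPH, rose by 0.82 (SE 0.09, edgeR adjusted p = 0.0445). Entpd4b fell from 134 to 66.6 CPM (edgeR adjusted p = 0.0340), and Prxl2a and 3 gene models without a plain symbol fell too. Entpd4b has a near-identical copy, so its reads may be split and its value is uncertain. Pisd at 0.81 (SE 0.09, edgeR adjusted p = 0.0620) and Bex1 at -0.90 (SE 0.13, edgeR adjusted p = 0.164) did not pass. Gfap at 0.09 (SE 0.37), Mbp at 0.12 (SE 0.33) and Snap25 at 0.00 (SE 0.19), markers of astrocytes, myelin and neurons, did not pass.

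By camera, 2 brain lists were higher and 6 lower, of 24 tested. None was called with an estimated correlation: the integrated stress response list had adjusted p = 0.518 with an estimated correlation, and the other called lists adjusted p = 0.725. That list had 15 of 20 members lower (median -0.19), with 1 down adjusted over the list alone and 0 over all genes, and included the factor Atf4 at -0.34 (SE 0.08) and its target Asns at -0.39 (SE 0.12). Oxidative phosphorylation subunits were lower in 68 of 74 (median -0.12), with Uqcr10 at -0.54 (SE 0.19) and 0 passing by either adjustment. This list was lowest in KO replicate 1 and stood at 6.25 to 6.40 log2 CPM in the other libraries. Its difference of group means went from -0.15 to -0.05 without KO replicate 1 (camera adjusted p = 0.0472, alternatives 5.66e-11 to 0.725). The circadian list was higher in 19 of 21 (median 0.17), with Arntl at 0.32 (SE 0.12) and 0 passing. The astrocyte list was higher in 13 of 16 (median 0.10), with 2 up adjusted over the list alone and 0 over all genes, the gap junction gene Gjb6 at 0.54 (SE 0.13) and Aldh1l1 at 0.37 (SE 0.09). It was not called without WT replicate 2 (camera adjusted p = 0.277), KO replicate 1 (0.0584) or KO replicate 3 (0.418, alternatives 0.0103 to 0.725). Its difference of 0.10 became 0.05 without WT replicate 2, 0.18 without KO replicate 2 and 0.03 without KO replicate 3. Red cell markers were lower in 6 of 8 (median -0.48), with 2 down adjusted over the list alone, 0 over all genes, and Hba-a1 at -0.76 (SE 0.20).

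Markers of brain regions differed between single libraries. The striatum list was lower in 13 of 14 members (median -0.99, 0 passing), with Gng7 at -0.85 (SE 0.31) and Adcy5 at -0.81 (SE 0.33). It stood at 4.61 log2 CPM in WT replicate 3, 4.57 in KO replicate 1 and 4.44 in KO replicate 3, and at 6.21 to 6.85 in the others, and was not called without WT replicate 1 (camera adjusted p = 0.103), WT replicate 2 (0.137) or KO replicate 1 (0.0732, alternatives 7.63e-11 to 0.725). Its difference of group means went from -0.96 to -0.55 without WT replicate 1, to -1.67 without WT replicate 3 and to -1.52 without KO replicate 2. The choroid plexus list was lower in 12 of 13 (median -1.54, 0 passing), with Clic6 at -1.29 (SE 0.48), and was highest in WT replicate 3, at 3.02. It was not called without that library (camera adjusted p = 0.541) or KO replicate 2 (0.402, alternatives 0.000146 to 0.725). Its difference of -0.97 became -0.19 without WT replicate 3, -1.62 without KO replicate 1 and -0.31 without KO replicate 2. The hypothalamus and pituitary list was lower in 8 of 8 (median -1.07, 0 passing), with Trh at -2.53 (SE 0.76), and was not called without WT replicate 1 (camera adjusted p = 0.0653) or KO replicate 2 (0.0611, alternatives 0.000230 to 0.725). The edgeR count of 7 became 4 without WT replicate 1, 4 without WT replicate 3, 1 without KO replicate 1 and 1 without KO replicate 3, while DESeq2 called 56, limma-voom 2 and a fit with the striatum level as a covariate, chosen after seeing the data, 11. Splits that mix the genotypes gave up to 21 genes and 12 lists.

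In liver, 71 genes rose and 66 fell, of 12331 tested. Among the rises were Nnt at 1.66 (SE 0.08, edgeR adjusted p = 5.08e-05, n = 3 per group), Pik3c3, the class III phosphoinositide kinase, at 1.66 (SE 0.14), Camk2b at 1.57 (SE 0.21), the lipid droplet protein Plin4 at 1.49 (SE 0.28), Ppp1r3c, which targets a phosphatase to glycogen, at 1.40 (SE 0.25), and Carmil1 at 1.33 (SE 0.15). Among the falls were Ntrk2, the BDNF receptor, at -2.20 (SE 0.36), Lamc3, a laminin chain, at -1.71 (SE 0.19), Ifi27l2b at -1.42 (SE 0.22) and Spp1, which encodes osteopontin, at -1.40 (SE 0.13). Cyp2a22 at -4.92 (SE 0.21) and Sult2a2 at -4.29 (SE 0.69) passed, but both belong to families of similar genes and are uncertain. Nr1d1 at -0.82 (SE 0.15) and Nr1d2 at -0.49 (SE 0.08), repressors of the circadian clock, fell, while Saa4 at 0.79 (SE 0.12), Cbr1 at 0.52 (SE 0.08) and Prxl2b at 0.79 (SE 0.12) rose. The liver lists of circadian, acute phase, NRF2 target and peroxiredoxin genes were not called (camera adjusted p = 0.927, 0.296, 0.484 and 0.668). Il1rn, an interleukin-1 receptor antagonist, fell by 1.54 (SE 0.29).

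By camera, 4 liver lists were higher and 4 lower, of 26 tested, and none was called with an estimated correlation. The chaperone and heat shock list was higher in 25 of 26 members (median 0.56), with 19 up adjusted over the list alone and 1 over all genes, and had adjusted p = 0.717 with an estimated correlation. Hspb1, a small heat shock protein, rose by 1.24 (SE 0.23). The other called lists had adjusted p = 0.757 with an estimated correlation. The cholesterol synthesis list was lower in 21 of 22 (median -0.57), with 14 down adjusted over the list alone and 3 over all genes: Hmgcs1 at -1.33 (SE 0.19), Msmo1 at -1.16 (SE 0.19) and Hsd17b7 at -0.59 (SE 0.08), all enzymes of the pathway. The stromal and matrix list was lower in 26 of 27 (median -0.58), with 13 down adjusted over the list alone and 1 over all genes, the collagen Col1a1 at -1.31 (SE 0.23). The male-predominant list was higher in 17 of 23 (median 0.64), with 9 up adjusted over the list alone and 3 over all genes: the transporter Slco1a1 at 2.22 (SE 0.42), Hsd3b5 at 2.77 (SE 0.53) and Mup11 at 2.14 (SE 0.22), the last from a family of near-identical genes and uncertain. The female-predominant list was not called (camera adjusted p = 0.232). It had 14 of 23 members lower and 9 higher (median -0.22), with 5 down and 2 up adjusted over the list alone.

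Another 4 liver lists were called by camera, and none of them with an estimated correlation. Oxidative phosphorylation subunits were higher in 69 of 74 (median 0.13), with Cycs at 0.27 (SE 0.08) and 0 passing by either adjustment. Their difference of group means in log2 CPM, 0.14, was 0.22 without WT replicate 1 and 0.09 without KO replicate 3. The fatty acid oxidation list was higher in 16 of 24 (median 0.20), with Cpt2 at 0.33 (SE 0.10) and 0 passing by either adjustment, and was not called without WT replicate 1 (camera adjusted p = 0.131), WT replicate 2 (0.411) or KO replicate 2 (0.512, alternatives 0.000441 to 0.757). Its difference of 0.17 became 0.06 without WT replicate 2, 0.35 without WT replicate 3, 0.31 without KO replicate 1 and 0.04 without KO replicate 2. The lipogenesis list was lower in 17 of 22 (median -0.48), with 1 down adjusted over the list alone, 0 over all genes, and Elovl5 at -0.54 (SE 0.12), and was not called without WT replicate 1 (camera adjusted p = 0.135), KO replicate 2 (0.101) or KO replicate 3 (0.0726, alternatives 1.01e-06 to 0.757). Its difference of -0.40 became -0.26 without WT replicate 1 and -0.64 without KO replicate 1. The immediate early list was lower in 12 of 14 (median -0.46), with 5 down adjusted over the list alone, 0 over all genes, Btg2 at -1.26 (SE 0.30) and Junb at -1.27 (SE 0.34). It stood at 4.79 log2 CPM in WT replicate 3 and at 3.11 to 3.64 in the other libraries, and was not called without WT replicate 3 (camera adjusted p = 0.218), KO replicate 1 (0.135) or KO replicate 2 (0.0538, alternatives 0.00351 to 0.757). Its difference of -0.63 became -0.24 without WT replicate 3. Alb at 0.01 (SE 0.22), Fasn at -0.48 (SE 0.40), Mat1a at -0.25 (SE 0.15) and the bile acid enzymes Cyp7a1 at -0.63 (SE 0.25) and Cyp8b1 at -0.88 (SE 0.30) did not pass. The edgeR count of 137 became 78 without WT replicate 1, 58 without WT replicate 2, 85 without WT replicate 3 and 87 without KO replicate 1, and DESeq2 called 402. The count of lists became 5 without KO replicate 2, and splits that mix the genotypes called up to 13 lists.

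Genes changed in the same direction in at least 2 tissues numbered 15 besides Prxl2a, with 9 higher and 6 lower in KO. Of the 15, 7 had a plain symbol. BAT and liver shared 8 rises, against 0.255 by chance (Fisher's exact test, adjusted p = 3.78e-10), and 6 falls against 0.0530 (Fisher's exact test, adjusted p = 3.63e-11). Of those 8 rises, only Pik3c3 and Wdfy1 had a plain symbol, and the rest were gene models that can share reads with copies elsewhere. Brain and liver shared 2 rises and 3 falls, and BAT and brain 1 rise and 3 falls. These chance values take the tissues as independent, although they may come from the same mice. IAT had 0 calls in edgeR and so shared none. Wdfy1 rose in BAT, brain and liver, by 1.23, 1.17 and 0.65 on the log2 scale. Nnt rose in brain and liver and had 0.51 in BAT (SE 0.29) and 1.22 in IAT (SE 0.16). It lies on chromosome 13, at 119335527 to 119409257, near Tmem267 at 119488086, which fell in BAT and liver. Whether a strain difference between KO and WT mice accounts for the change of either gene was not tested. Pik3c3 rose in BAT by 0.88 and in liver by 1.66. Entpd4b fell in BAT, brain and liver, with log2 fold changes of -1.36 in BAT and -0.68 in liver and with the uncertainty of its near-identical copy. The gene models Gm29804 and LOC100041599 fell in those 3 tissues, with log2 fold changes of -7.06 to -3.91 and of -7.64 to -7.08. Gm41885, LOC115488503, Gm40525 and Gm42102 rose in BAT and liver, with liver log2 fold changes of 1.87, 2.38, 1.97 and 1.46. Such gene models can share reads with copies elsewhere and are uncertain.

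**Figure D4:**
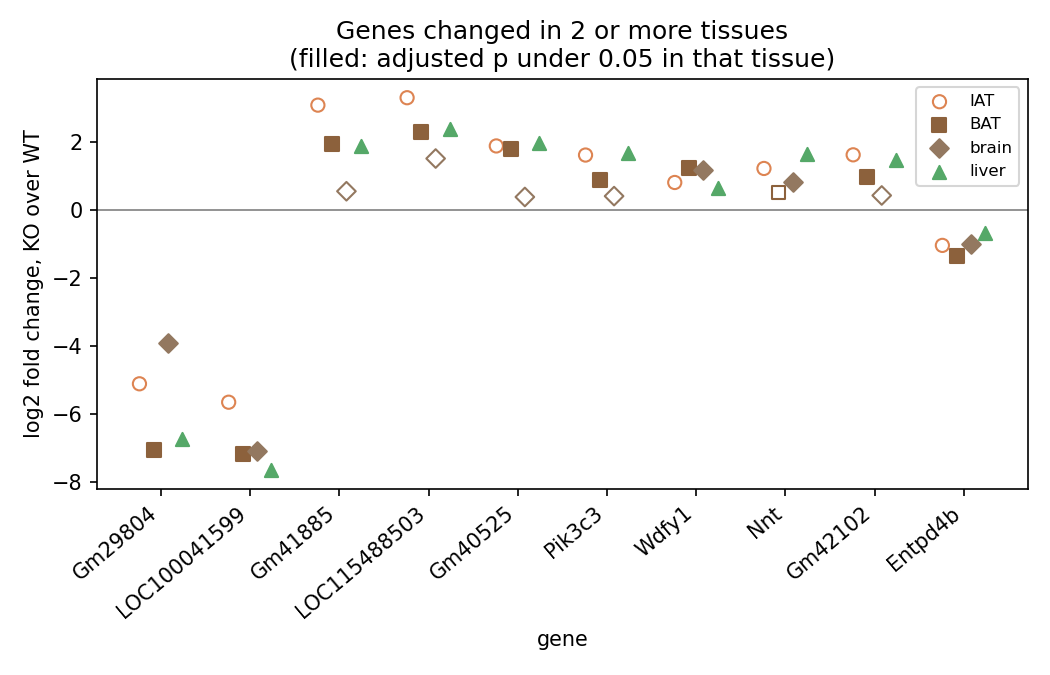
Log2 fold change of 10 genes changed alike in at least 2 tissues, with 1 marker shape per tissue. Filled markers passed at an adjusted p under 0.05 in edgeR, and no IAT marker is filled. Wdfy1 was at 1.23 in BAT, 1.17 in brain and 0.65 in liver.

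The KO change differed between tissues for 68 of 16169 genes in edgeR. The tissue farthest from the mean of the others was IAT for 31 of them, BAT for 14, liver for 14 and brain for 9. The interaction test shares a single dispersion per gene over all tissues, although IAT varied more. As a coefficient of variation, the common dispersion was 0.329 in IAT and 0.131 to 0.169 in the other tissues. The same fit of all 24 libraries called 2573 genes in IAT, so differences that rest on IAT may be called too readily. Fitted on its own libraries, IAT had 0 calls, and 2 of the 68 genes were in the lymphocyte or muscle lists. These lists hold only 30 and 22 genes, so this count does not show how many of the 68 reflect other cell types. Ube2ql1 had 2.14 in BAT and -0.11 in brain, a difference of 2.25 (SE 0.22, edgeR adjusted p = 6.31e-05). Gja1, a gap junction gene, had 0.82 in BAT and -0.99 in IAT, which differed by -1.82 for IAT minus BAT (SE 0.27, edgeR adjusted p = 0.00843). The count became 245 without WT replicate 1 of each tissue, 10 without WT replicate 2, 28 without WT replicate 3, 16 without KO replicate 1, 2063 without KO replicate 2 and 3 without KO replicate 3, and the DESeq2 likelihood ratio test gave 1225.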

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

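All tests of explanations in this part were fixed before their result was seen, except that of a genotype effect on lymphocytes, which was chosen only after it was seen. Each of the following genes had a KO change that differed between tissues in edgeR's interaction test, where IAT was the farthest tissue for 31 of 68 genes. That test shares a single dispersion per gene over all tissues although IAT varied more, so calls that rest on IAT may be overstated. Of the 68, 2 were in the lymphocyte or muscle lists, which hold only 30 and 22 genes and cannot count all transcripts of such cells. Ube2ql1 (adjusted p = 0.000891) had its largest value in BAT, at 2.14. Gldn (adjusted p = 0.00563) was at 0 counts in all KO liver libraries and so at least 12.9-fold lower there, with the floor of 3 counts taken over the group. Gprc5c (adjusted p = 0.00563) had -1.36 in IAT and 0.75 in BAT. Pik3c3 (adjusted p = 0.00750) had 1.60 in IAT, 0.87 in BAT, 0.40 in brain and 1.65 in liver. Plekha6 (adjusted p = 0.0117) had -1.52 in BAT and 0.33 in brain. Rogdi (adjusted p = 0.0117) had 1.06 in IAT and -0.32 in liver. Gja1 (adjusted p = 0.0162) had -0.99 in IAT and 0.82 in BAT.

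Lymphocyte transcripts were high in KO replicates 1 and 3 of IAT and low in KO replicate 2. A candidate explanation is lymph node in the piece of tissue, since inguinal fat surrounds one. Of 8 detected genes of lymph node vessels and stroma, a list apart from the lymphocyte list, 4 were at least 4 times higher in both libraries than in each of the others, short of the 3 in 4 set beforehand, so the test left it open. Ccl19 stood at 141 and 68.4 CPM against at most 1.26 CPM elsewhere, while Cxcl13 was at 138 and 86.9 CPM against up to 97.9 CPM in WT. An effect of the genotype on lymphocytes in fat cannot be told apart from this: KO replicate 2 lay at -1.25 log2 against the highest WT library, but 1 library excludes nothing.

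Muscle transcripts were high in WT replicates 1 and 2 of IAT. Skeletal muscle in the piece of tissue may account for them: 11 of 15 further muscle genes were at least 4 times higher in both libraries than in each of the others, also short of the 3 in 4 set beforehand, so the test left it open. This outcome turned on the cut for a detected gene, 1 CPM in at least 1 library: Cacng1, at most 2.13 CPM, was among those not counted as higher, and without it the share would be 11 of 14, past 3 in 4. No biological explanation was tested for this pattern.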

How the results depend on the processing

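Alternatives added only after seeing the data were the robust prior, the covariates and the joint removal of IAT libraries; all others were planned. RLE normalization changed no count of genes or lists within a tissue by more than 1.5 times, and the median of all genes moved by -0.013 on the log2 scale in IAT and by -0.0031 to 0.00071 in the other tissues. The cause of the changes below was not tested. For genes changed, DESeq2 gave 987 in IAT, 467 in BAT, 56 in brain and 402 in liver, limma-voom 7 in IAT and 2 in brain, and all 24 libraries in 1 fit 2573 in IAT and 173 in BAT. No filter gave 218 in liver. An absolute log2 fold change of at least 1, which can only remove calls, left 37 in BAT and 85 in liver. Limma-trend on TPM gave 29 and 28 in BAT. The striatum covariate gave 11 in brain. Leaving out 1 library gave 0 to 1760 in IAT, 2 to 94 in BAT, 1 to 9 in brain and 58 to 103 in liver, with fewer samples in each fit.

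Lists called fell to 0 in every tissue with an estimated correlation, and fry gave 1 in IAT and 0 in BAT, brain and liver. Without 1 library they numbered 9 to 15 in IAT, 4 to 8 in BAT, 6 to 12 in brain and 5 to 12 in liver. The interaction gave 103 with RLE, 1225 with the DESeq2 likelihood ratio test and 3 to 2063 without 1 animal number. Changed genes shared between tissues numbered 122 with calls by DESeq2. Prxl2a in IAT passed with DESeq2 at -4.59, limma-voom at -4.66, all 24 libraries at -4.58, and without 1 library it ranged from -4.95 to -4.31.

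The labels give WT and KO the same replicate numbers. Deviations of same-numbered libraries correlated at -0.23 to 0.03 in IAT, -0.24 to -0.17 in BAT, 0.04 to 0.39 in brain and -0.07 to 0.20 in liver across genes. Libraries that correlated best with their own number were 0 in IAT, 0 in BAT, 4 in brain and 3 in liver. The numbers thus did not pair the libraries in IAT or BAT, while pairing stays open in brain and liver. With the replicate block, edgeR called 0 genes in IAT, 1 in BAT, 4 in brain and 228 in liver, 11, 4, 8 and 9 lists, 37 genes in the interaction and 2 shared genes.

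Of 403 alternative values of called genes in BAT, 249 stayed called, as did 42 of 75 in brain and 390 of 519 in liver, and none changed sign. Of the values of genes that did not pass, 10 of 508 changed sign in IAT, 10 of 225 in BAT, 9 of 389 in brain and 5 of 150 in liver, and 91, 6, 15 and 5 passed. Pparg in IAT was -0.13 with limma-voom, -0.11 with the block and -0.056 and -0.057 with limma-trend on log2(TPM + 1) and log2(TPM + 0.1). With the same pair, Adipoq in BAT was -0.0592 and -0.0592, Lep in BAT -0.12 and -0.13 and Alb in liver -0.075 and -0.075. Lep in BAT was -0.029 with limma-voom and -0.0047 with the block, and Snap25 in brain -0.00098 with all 24 libraries. Without 1 library, Adipoq in IAT ranged from -0.44 to 0.28, Pparg in IAT from -0.50 to 0.38, Fasn in BAT from -0.41 to 0.028, Ifit1 in BAT from -0.22 to 2.34, Lep in BAT from -0.21 to 0.55, Gfap in brain from -0.15 to 0.50, Mbp in brain from -0.18 to 0.46, Snap25 in brain from -0.17 to 0.18 and Alb in liver from -0.073 to 0.11.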

Other observations

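The tests of chromosome 14, strain background and predicted gene models in this part were chosen only after the pattern was seen, and the counts over other splits of the libraries were planned. In BAT, the interferon list stood at 5.51 log2 CPM in KO replicate 2 and at 3.64 to 4.21 in the other libraries, and Ifit1 had a log2 fold change of 1.87 (SE 0.91, n = 3 per group) that did not pass and was -0.22 without KO replicate 2. In liver, red cell markers stood at 5.06 in WT replicate 1 and 4.83 in KO replicate 1, and at 3.43 to 3.87 in the others.

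Of 11027 genes tested in all 4 tissues, 33 besides Prxl2a had KO libraries on the same side of all WT libraries in every tissue, 27 higher and 6 lower. The 10 splits of the replicate numbers made alike in all tissues are too few for a share under 0.05, with 33 genes in the real split, 1 split reaching it, and at most 1 gene in the others. Splits drawn apart in each tissue gave at most 5 genes in 100 draws, but these were added after the pattern was seen and treat the tissues as independent, although they may come from the same mice. Deviations from the group mean of same-numbered libraries of different tissues correlated at means of -0.01 to 0.04 across genes, which leaves that open, so these draws were not used to exclude chance. An interval of chromosome 14 inherited with the targeted allele is a candidate explanation for the 3 located there. Their share was 11.5% against 3.33% of other genes (Fisher's exact p = 0.0550), which leaves it open. The test counted the whole chromosome without regard to distance. Plac9b starts at 26167316, Gm43305 at 54292441 and Entpd4b at 69555401, on both sides of Prxl2a at 40993735. Entpd4b has a near-identical copy and is uncertain. The 23 genes on other chromosomes lie outside such an interval, and splits that mix the genotypes gave at most 1 there. Whether the interval could act on genes elsewhere was not tested, so this count does not exclude it for them.

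A different strain background of the KO mice also stays open for the 33 genes, and the labels used here give no strain. Of the 26 with coordinates, 4 had another within 1 Mb, against a mean of 1.06 in random sets (permutation p = 0.0915). They were Fam177a with Srp54b on chromosome 12, and 9030025P20Rik with Gm3435 on chromosome 17. Differences scattered over the genome need not give neighbours, so this test cannot decide on strain. Nnt and Tmem267 were not among the 33, so this test did not cover them. Among the 33, 17 genes without a plain symbol, here called predicted gene models, were higher in KO. This class takes in Gm and LOC names, Rik clones, pseudogenes and bare identifiers. A general rise of all such models needed a class median of at least 0.3 in every tissue. In BAT the class median was -0.038 (bootstrap SD 0.02, SD of the 425 members 0.77), which argues against a rise of this whole class there. A rise of Gm and LOC names alone was not tested. The 17 had a median of 1.18 in BAT, but they were picked as higher in every tissue. Comparing them with the class, a condition added after the first result was known, therefore decides nothing. The class medians were -0.0031 in brain, 0.0094 in liver and 0.16 in IAT (SD of the members 1.12), where 332 of 520 were higher, so a smaller rise in IAT stays open. Reads shared between copies of a repeated sequence may play a part, but only 3 of the 17 could be looked up in reference transcripts, of which 2 shared a stretch of 50 bases, so this test was void.

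The 10 splits of the 6 libraries of a tissue are too few for a share under 0.05. In IAT, the real split gave 0 genes by edgeR and the others at most 0, so all 10 reached it, and it gave 11 lists against up to 15, reached by 8 splits. In BAT, the real split gave 68 genes against at most 1, reached by 1 split, and 5 lists against up to 11, reached by 9 splits. In brain, the real split gave 7 genes against up to 21, reached by 2 splits, and 8 lists against up to 12, reached by 6 splits. In liver, the real split gave 137 genes against 0, reached by 1 split, and 8 lists against up to 13, reached by 6 splits. For the interaction, 2 of 50 drawn splits, the real one included, gave at least its 68 genes, with 72 as the highest other. That share is under 0.05, but it rests on 1 draw and, as above, on splits drawn apart in each tissue.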
